A study of Mus musculus with 24 samples.

How the data were processed

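RNA was measured in the livers of 24 female NSG mice, an immunodeficient strain. The labels give an age of 8 weeks, taken here as the age at the start of treatment. Mice were injected into the tail vein 2 times a week for 5 weeks with phosphate-buffered saline (PBS) or with about 10 µg of extracellular vesicles (EVs, membrane particles released by cells), and the liver was taken 2 days after the last injection. RNA was extracted with TRIZOL and made into libraries with a stranded mRNA kit, per the labels' protocols.

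The deposited values are read counts per gene symbol, whole numbers without normalization, in 1 table of 23240 rows. Per the submitters' processing notes, bcl2fastq 2.18.0.12 and TopHat2 were used with the mouse build mm9. The counting tool, its annotation, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Reads of genes with near-identical copies, of overlapping genes and of antisense partners could therefore have been split or lost, and genes of this kind are named as uncertain. Every row names a gene. The 27 rows that share 11 symbols (0.0744% of all counts) were left out of the tests.

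Libraries were grouped by the treatment label, which matches the title: PBS, MCF10A EV, MCF10A/miR-122 EV and MDA-MB-231 EV, 6 libraries each. For 12 libraries the library names contradict this label. The 6 libraries labelled MCF10A/miR-122 EV have names that read 231-exo, and the 6 labelled MDA-MB-231 EV have names that read 122 or 10A-122-exo. These groups are called by their label throughout, and the comparisons were repeated with the identities taken from the library names. The comparisons of all EVs and of MCF10A EV with PBS do not depend on this choice. Each library is taken as 1 mouse, although the labels do not state it in so many words. If libraries shared a mouse, p-values would measure technical spread.

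Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group and all 24 libraries in 1 fit with a mean per group. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 13773 genes tested, and the threshold was an adjusted p of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM, the scaled counts of edgeR's cpm function, on TMM-scaled library sizes, given as mean ± SD. The count table gave totals of 21.3 to 33.7 M (mega) counts per library, and the common biological coefficient of variation was 16.8%. On simulated counts for the comparison of MDA-MB-231 EV with PBS, over 13660 genes, 49 of 67 genes changed 1.5-fold (73.1%), 65 of 67 changed 2-fold (97%) and all 66 changed 4-fold were recovered, and 4 of 199 calls were false (2.01%). None of the 99 unchanged lists was called, but the simulated genes varied independently of each other. Real list members did not: the estimated correlation was 0.844 for the ribosomal protein genes in all EVs against PBS. The simulation therefore does not test false list calls on these data.

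The tests, the lists of 37 gene groups, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Of the lists, 35 had the 5 tested members required. The pancreatic acinar and lymphocyte lists had 3 each and were not tested. Lists were tested with camera in limma 3.58.1 on voom log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. The test was repeated with an estimated correlation and with fry. With the estimated correlation only the circadian list held, in the comparisons of each of the 2 last groups with MCF10A EV.

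Genes named in the text come from a rule. For each comparison it takes the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 1 and a direction against the reference group's median in at least 5 of 6 libraries of each named group (15 of 18 for all EVs), without predicted loci. It adds the 4 members with the smallest p of each list past the set test, up to 8 reported miR-122 targets past the threshold, and the 2 markers with the smallest p of each cell type list whose median log2 fold change was over 0.5 in size. With fewer than 5 genes past the threshold it would have taken the 8 smallest p, which did not arise. The rule gave 46 to 74 genes per comparison. Values are printed for 17 to 33 of them, and this selection among the rule's genes was made after their values were seen.

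Sequence shared between genes was measured on GENCODE M21 transcripts as the percent of 32-mers found in another gene, and 10% or more marks a multi-copy gene. That annotation is of another build than the deposited counts, so it served only for names and sequences: 98.2% of symbols matched, and no coordinates are given. Matches to the miR-122 seed (7mer-m8, with 8mer and with 7mer-m8 or 7mer-A1 as alternatives) were searched in annotated 3' UTRs.

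The alternatives tried were RLE size factors, no filter on low counts, a strict filter (5 CPM in 6 libraries), DESeq2 1.42.0, limma-voom with quality weights, a fit of only the compared groups, the replicate number as a block, a further limit of 2-fold, group identity from the library names, and leaving out each library in turn. After the data were seen, 2 were added: without multi-copy genes, and without PBS replicate 5 and MCF10A EV replicate 4. Among the 60 pairs of libraries within a group none was identical, and the mean chi-square per gene of a pair was 14.9 to 139, against about 1 for sampling noise alone.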

Results

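The livers of mice given EVs of breast epithelial or breast cancer cells were compared with those of mice given PBS, and with each other. The 24 libraries fell into 2 sets of 12. In the 12 PBS and MCF10A EV libraries, which carry the first numbers in the library names, Serpina3a, a serine protease inhibitor gene, was at 109.6 to 325 CPM. In the 12 libraries labelled MCF10A/miR-122 EV and MDA-MB-231 EV it was at 0.285 to 5.85 CPM. Ptcra, the pre-T-cell receptor alpha gene, had 47 to 143 counts in the first set and 0 to 1 in the last, and the predicted gene Gm5779 had 39 to 63 and 0 to 1. These last 2 genes were chosen after their values were seen. The sets also differed in total counts (25.9 ± 2.53 M against 30.9 ± 1.95 M) and on the first principal component of log2 CPM, which held 23.0% of the variance (-27.1 to -8.10 against 8.89 to 30.8). No group had libraries in both sets, so in the 4 comparisons that cross them, and in part in that of all EVs with PBS, the set and the treatment cannot be told apart. The comparisons of MCF10A EV with PBS and of the 2 last groups with each other lie within a set. Values in parentheses after a gene are log2 fold changes, and each gene had its direction in 6 of 6 libraries of the first-named group unless a count is given.

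**Figure D1:**
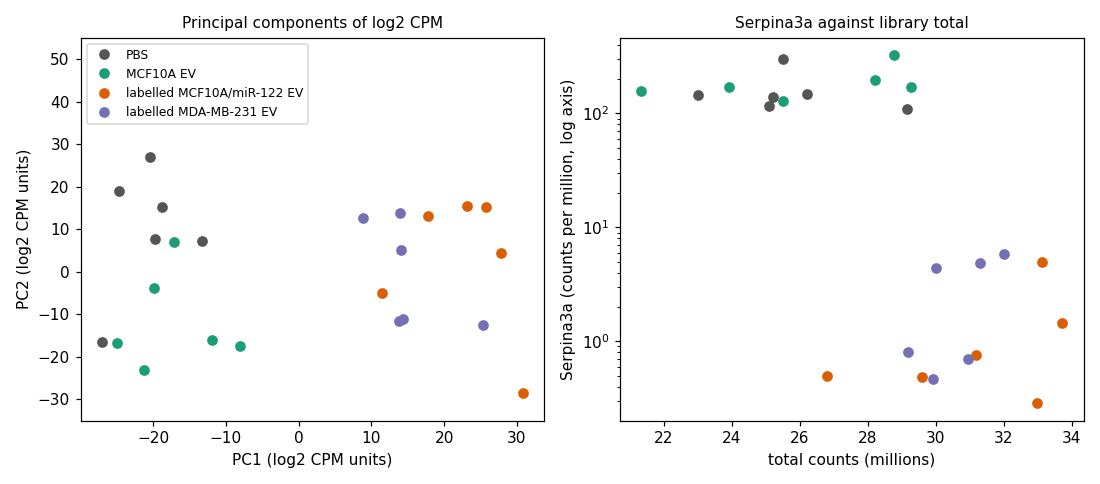
Left, the first and second principal components (PC1 and PC2, log2 CPM units) of the 24 libraries, 1 point per library, colored by group as labelled. Right, Serpina3a in CPM (log axis) against total counts in M. The PBS and MCF10A EV libraries have Serpina3a at 109.6 to 325 CPM and the other 12 at 0.285 to 5.85 CPM.

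Livers given MCF10A EVs had less Ccnd1 RNA and more RNA of Hp, Lcn2 and Tsc22d3 than livers given PBS. Ccnd1, which encodes cyclin D1, was at 36.6 ± 7.89 CPM with MCF10A EVs and 88.4 ± 12 CPM with PBS (mean ± SD, n = 6 each; log2 fold change -1.27, SE 0.18, adjusted p = 0.00328). Hp, the gene of the hemoglobin-binding plasma protein haptoglobin, was at 2800 ± 325 and 1800 ± 162 CPM (log2 fold change 0.64, SE 0.10, adjusted p = 0.00574). Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose by a log2 fold change of 1.23 (SE 0.23, adjusted p = 0.0131), and Tsc22d3, a glucocorticoid-induced gene, by 1.12 (SE 0.21, adjusted p = 0.0135).

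Of 31 cell cycle genes, 5 fell and none rose, and 24 passed when adjusted over the list alone. Besides Ccnd1, the proliferation marker Mki67 had a log2 fold change of -1.62 (adjusted p = 0.0397), Top2a, a DNA topoisomerase gene, -1.62 (adjusted p = 0.033) and Cdc20, an activator of the anaphase-promoting complex, -2.07 (adjusted p = 0.0397). Cdc20 shares 26.1% of its 32-mers with other genes and was at 0.435 CPM with MCF10A EVs. PBS replicate 3 was at 16.3 CPM of Mki67, the other PBS libraries at 1.93 to 5.29 CPM, and without it Mki67 had -0.93 (adjusted p = 0.14), Top2a -1.11 (adjusted p = 0.101) and Cdc20 -1.55 (adjusted p = 0.152), none of them past the threshold. The median of the list was -0.87 (camera adjusted p = 2.56e-11, adjusted p = 0.243 with an estimated correlation). Of 32 acute phase genes 4 rose, and 15 passed adjusted over the list alone (median 0.25, camera adjusted p = 5.35e-07, adjusted p = 0.243 with an estimated correlation). They were Hp, Lcn2, the interleukin 1 receptor gene Il1r1 (0.86, adjusted p = 0.0152) and the plasma protease inhibitor component Itih3 (0.41, adjusted p = 0.00851).

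**Figure D2:**
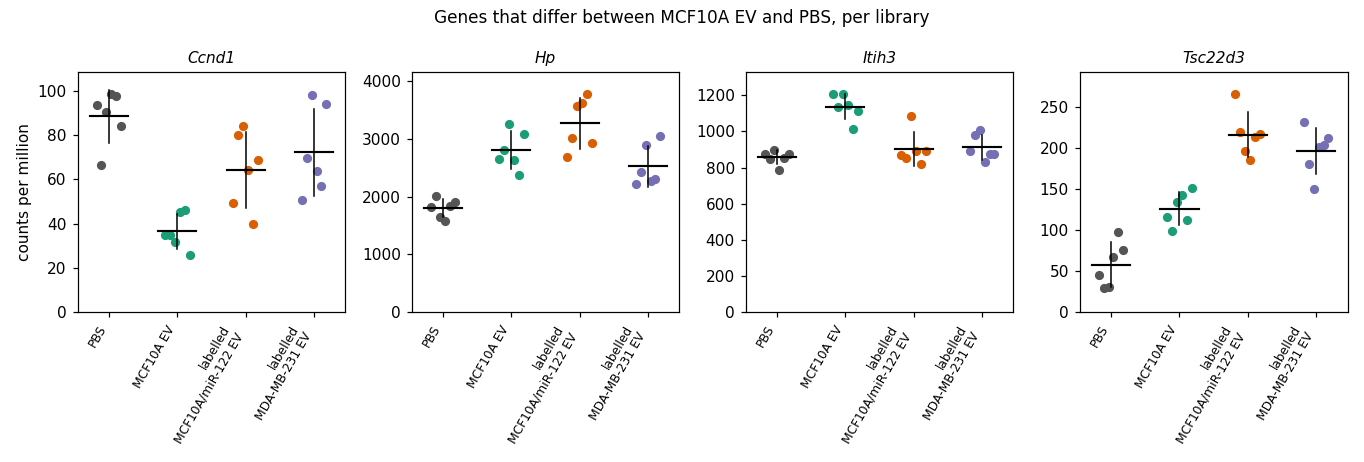
Ccnd1, Hp, Itih3 and Tsc22d3 in CPM (linear axis from 0), 1 point per library, with the mean (horizontal line) and SD (vertical line) of the 6 libraries of each group. Ccnd1 averages 88.4 ± 12 CPM with PBS and 36.6 ± 7.89 CPM with MCF10A EVs.

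Of 21 circadian genes 4 fell and none rose, and 11 passed adjusted over the list alone. The list did not pass camera (adjusted p = 0.136, adjusted p = 0.455 with an estimated correlation). Camera looks for a shift in 1 direction, and this list holds genes of opposite phase. Fry for mixed directions passed (adjusted p = 0.00434), and did so without each of the 12 libraries in turn. Dbp, a transcription factor driven by the core clock, had a log2 fold change of -2.43 (SE 0.53, adjusted p = 0.0251), the clock repressor gene Per3 -2.05 (SE 0.43, adjusted p = 0.0192) and Wee1, a clock-driven kinase gene of mitotic entry, -2.08 (SE 0.35, adjusted p = 0.00712). PBS replicate 5 was at 3.57 CPM of Dbp, within the range of the MCF10A EV libraries. Cux2, a transcription factor gene of female liver, fell with a log2 fold change of -1.69 (adjusted p = 0.0131), and so did the near-identical cytochrome P450 genes Cyp2a5 (-1.37, adjusted p = 0.0144) and Cyp2a4 (-1.30, adjusted p = 0.0221), whose reads may have been shared, and the growth arrest gene Gadd45a (-1.56, adjusted p = 0.033). Among female-biased genes 2 of 20 fell, and 5 passed adjusted over the list alone (camera adjusted p = 4.83e-05, adjusted p = 0.243 with an estimated correlation). Other rises were Banp (1.05, adjusted p = 0.0273), Eif4ebp3, a multi-copy gene of a translation inhibitor (1.03, adjusted p = 0.0397), Ablim3 (0.94, adjusted p = 0.0152), Arhgef26 (0.91, adjusted p = 0.0152) and the lipoprotein lipase inhibitor gene Angptl4 (0.83, adjusted p = 0.0268).

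Of 18 heat shock genes none passed over all genes and 11 passed adjusted over the list alone (camera adjusted p = 6.51e-09, adjusted p = 0.3 with an estimated correlation). The multi-copy chaperone gene Hspa8 had a log2 fold change of 0.61 (adjusted p = 0.075). Of 28 genes of the unfolded protein response 1 rose, the chaperone gene Calr (0.37, adjusted p = 0.0383), and 13 passed adjusted over the list alone (camera adjusted p = 6.69e-06, adjusted p = 0.3 with an estimated correlation). No single gene passed, over all genes, among 63 ribosomal protein genes (Rps12, multi-copy, 0.32, adjusted p = 0.158), 20 hepatocyte markers (Apoh, 0.28, adjusted p = 0.0688) or 39 interferon-stimulated genes (Cxcl10, -1.10, adjusted p = 0.0551). Adjusted over the list alone, 0, 2 and 2 passed. Their camera adjusted p were 2.97e-17, 4.16e-06 and 0.0366, and with an estimated correlation the adjusted p were 0.535, 0.243 and 0.972.

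In all, 147 of 13773 genes passed, 51 higher and 96 lower, and 2383 had an unadjusted p under 0.05. The count was 741 without PBS replicate 5 and 26 without PBS replicate 3, 27 when only these 12 libraries were fitted, 414 with DESeq2 and 837 with limma-voom. The excess of falls turned with limma-voom (441 higher and 396 lower) and in the fit of these 12 libraries (14 and 13). Without PBS replicate 5 the counts were 350 and 391. The excess held with DESeq2 (158 and 256), RLE size factors (51 and 114) and the strict filter (39 and 94). Ccnd1, Hp, Itih3, Lcn2, Tsc22d3, Wee1, Cux2 and Cyp2a5 passed without any 1 library, and the other 14 named genes that passed lost their call without at least 1.

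The group labelled MCF10A/miR-122 EV stood apart from that labelled MDA-MB-231 EV by its serum amyloid A genes, which encode acute phase apolipoproteins. Saa1 was at 566 ± 173 CPM in the first group and 38.6 ± 21.1 CPM in the second (n = 6 each), Saa2 at 361 ± 146 and 23.7 ± 16.4 CPM, and Saa3 at 67 ± 32.3 and 4.07 ± 0.954 CPM. The log2 fold changes, MDA-MB-231 EV over MCF10A/miR-122 EV as labelled, were -3.88 (SE 0.31, adjusted p = 3.21e-08), -3.92 (SE 0.41, adjusted p = 4.24e-06) and -4.04 (SE 0.27, adjusted p = 9.75e-10). All 6 libraries of the first group lay above the other 18, the lowest at 339 CPM of Saa1 against at most 80.6 CPM elsewhere. Saa1 and Saa2 share 21.6% and 20.1% of their 32-mers with other genes, so the division of reads between them is uncertain. The library names give these 2 groups the opposite identities, which turns the direction of each fold change in this comparison.

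**Figure D3:**
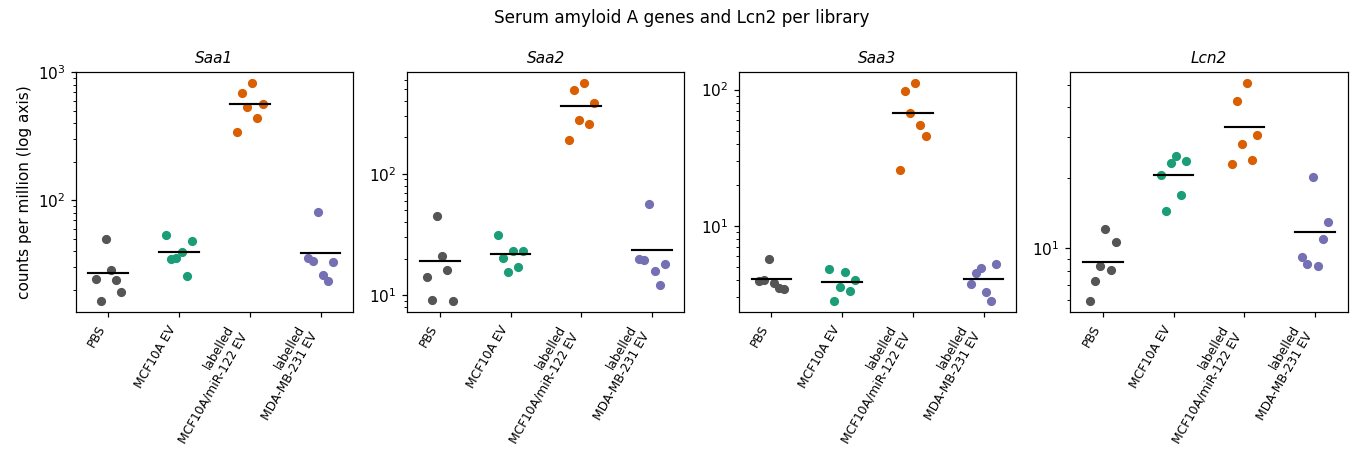
Saa1, Saa2, Saa3 and Lcn2 in CPM (log axis), 1 point per library, with a line at the mean of the 6 libraries of each group as labelled. For Saa1 the lowest library labelled MCF10A/miR-122 EV is at 339 CPM and the highest of the other 18 at 80.6 CPM.

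Lcn2 was also lower in the group labelled MDA-MB-231 EV (-1.49, adjusted p = 0.00122), as were the junctional adhesion gene Amica1 (-2.69, adjusted p = 2.41e-04), the potassium channel gene Kcna2 (-1.19, adjusted p = 0.00953) and BC018473 (-2.01, adjusted p = 0.0381). Of 32 acute phase genes 5 were lower, and 10 adjusted over the list alone (camera adjusted p = 1.66e-11, adjusted p = 0.103 with an estimated correlation). Of 22 macrophage markers 3 were lower: Cd5l (-1.12, adjusted p = 0.0161), Emr1, which encodes F4/80 (-1.13, adjusted p = 0.0373), and the complement receptor gene Vsig4 (-0.65, adjusted p = 0.0337). The scavenger receptor gene Marco had -1.04 (adjusted p = 0.0903). The list's median was -0.38, with 11 past adjusted over the list alone (camera adjusted p = 4.30e-13, adjusted p = 0.2 with an estimated correlation). Of 20 premetastatic niche factors 3 were lower, Saa1, Saa3 and Lcn2, and 5 adjusted over the list alone (adjusted p = 0.175 with an estimated correlation). The adhesion gene Vcam1 had -0.92 (adjusted p = 0.2).

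The 6 genes higher in the group labelled MDA-MB-231 EV included the bile acid synthesis genes Cyp8b1, a sterol 12-alpha-hydroxylase (1.31, adjusted p = 0.0214), and Cyp7b1, an oxysterol 7-alpha-hydroxylase more active in male liver (0.82, adjusted p = 0.0181). Fam198a (1.18, adjusted p = 0.0431), the multi-copy gene Gp49a (0.83, adjusted p = 0.0132) and the integrin-binding kindlin gene Fermt2 (0.33, adjusted p = 0.0214) were higher too. Cyp7b1 was the 1 male-biased gene of 21 past the threshold, with 9 past adjusted over the list alone (camera adjusted p = 1.61e-09, adjusted p = 0.174 with an estimated correlation). Genes that did not pass were the male-biased multi-copy gene Hsd3b5 (1.24, adjusted p = 0.145), the female-biased gene Cyp17a1 (-1.24, adjusted p = 0.0551), the serine dehydratase gene Sds (-0.55, adjusted p = 0.284, 5 of 6 libraries), and the multi-copy genes Hspa1a (0.80, adjusted p = 0.703) and Cyp2a5 (-0.94, adjusted p = 0.155).

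In all, 35 genes passed, 6 higher and 29 lower, and 1128 had an unadjusted p under 0.05. Without MCF10A/miR-122 EV replicate 3 the count was 13 and without replicate 4 it was 82, and it was 98 with DESeq2, 221 with limma-voom (88 higher and 133 lower), 23 when only these 12 libraries were fitted and 15 with the strict filter. Of the 15 named genes that passed, 7 did so whichever library was left out, and Cd5l, Emr1, Vsig4, BC018473, Cyp8b1, Cyp7b1, Fam198a and Fermt2 lost their calls without at least 1.

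Against PBS, the group labelled MCF10A/miR-122 EV, which bears the other group's name in the library names, had higher Saa1, Saa2, Saa3, Amica1 and Ppp1r3g. Log2 fold changes were 4.39 for Saa1 (SE 0.32, adjusted p = 6.86e-10), 4.25 for Saa2 (SE 0.42, adjusted p = 2.17e-07) and 4.04 for Saa3 (SE 0.27, adjusted p = 1.33e-10). With the identities of the library names Saa3 had a log2 fold change of -0.0014. Amica1 rose by 3.82 (adjusted p = 6.47e-07), the glycogen-targeting phosphatase subunit gene Ppp1r3g by 3.73 (adjusted p = 1.31e-04) and the insulin-repressed gene Igfbp1 by 2.48 (adjusted p = 0.00997, 5 of 6 libraries). Without replicate 3 of that group Ppp1r3g had 3.01 (adjusted p = 3.26e-04), and Igfbp1 had 1.60 and did not pass (adjusted p = 0.0589). Serpina3a (-6.79, adjusted p = 4.99e-08) and the multi-copy histone gene Hist1h2ak (7.97-fold lower, adjusted p = 8.05e-12) fell, both lower in all 12 libraries of the last set. Without replicate 6 of that group Serpina3a had -7.81.

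Of 17 gluconeogenesis genes 7 rose and 1 fell, and 10 passed adjusted over the list alone (median 0.67, camera adjusted p = 2.13e-04, adjusted p = 0.114 with an estimated correlation). Among them were the tyrosine aminotransferase gene Tat (1.56, adjusted p = 8.45e-05), the coactivator gene Ppargc1a (1.48, adjusted p = 0.00113) and the glucose 6-phosphate transporter gene Slc37a4 (0.67, adjusted p = 2.96e-04). Of 32 acute phase genes 12 rose, 13 adjusted over the list alone, among them Il1r1 (1.44, adjusted p = 2.80e-06) and Lcn2 (1.92, adjusted p = 3.64e-06) (camera adjusted p = 2.87e-09, adjusted p = 0.108 with an estimated correlation). Of 22 macrophage markers 10 rose, 14 adjusted over the list alone, such as Vsig4 (0.62, adjusted p = 0.00307) and Marco (0.97, adjusted p = 0.00911) (median 0.42, adjusted p = 0.62 with an estimated correlation). With the library names these 2 had -0.035 and -0.070. Vcam1, 1 of 5 niche factors of 20 that rose, had 1.24 (adjusted p = 0.00281, list adjusted p = 0.266 with an estimated correlation, 6 adjusted over the list alone).

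Of 21 circadian genes 8 rose and 2 fell, and 11 passed adjusted over the list alone (adjusted p = 0.108 with an estimated correlation). The clock-driven protease gene Usp2 (2.47, adjusted p = 2.45e-05) and the repressor gene Per2 (1.51, adjusted p = 8.92e-04) rose, and the clock activator genes Arntl (-2.09, adjusted p = 7.79e-04) and Npas2 (-3.71, adjusted p = 0.00317) fell. PBS replicate 5 was at 12.4 CPM of Npas2, and without it the log2 fold change was -2.09 (adjusted p = 0.0175). The lipogenic gene Thrsp rose by 2.04 (adjusted p = 3.71e-04), while the lipid droplet gene Plin2 (-0.96, adjusted p = 6.93e-04) and the carnitine palmitoyltransferase gene Cpt2 (-0.42, adjusted p = 0.00118) fell, as did 5 of 33 fatty acid oxidation genes against 1 that rose (6 adjusted over the list alone, adjusted p = 0.838 with an estimated correlation). Of 36 xenobiotic genes 8 rose (9 adjusted over the list alone, adjusted p = 0.55 with an estimated correlation), such as the P450 reductase gene Por (0.78, adjusted p = 0.00123) and Cyp1a2 (0.58, adjusted p = 0.00144). Of 39 interferon-stimulated genes 11 fell and 1 rose (17 adjusted over the list alone, adjusted p = 0.815 with an estimated correlation), among them the peptide transporter gene Tap1 (-0.84, adjusted p = 2.92e-04) and the chemokine gene Cxcl10 (-1.31, adjusted p = 0.00259).

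Of 30 reported miR-122 targets 6 fell and 1 rose, 7 adjusted over the list alone, and the list did not pass against other genes (camera adjusted p = 0.301, adjusted p = 0.66 with an estimated correlation). Fry, which does not compare it with other genes, passed downward (adjusted p = 0.0254; 1.98e-07 for mixed directions). The branched-chain ketoacid dehydrogenase kinase gene Bckdk (-0.60, adjusted p = 3.05e-04), the hemojuvelin gene Hfe2 (-1.06, adjusted p = 6.95e-04) and the chromatin remodeling gene Smarcd1 (-0.61, adjusted p = 0.00177) fell, and the collagen prolyl hydroxylase gene P4ha1 rose (1.14, adjusted p = 0.00471). The muscle actin gene Acta1 (-1.40, adjusted p = 5.97e-07) and the multi-copy ribosomal gene Rpl34 (-0.35, adjusted p = 0.00471) fell. In all, 2463 genes passed, 1150 higher and 1313 lower, in a comparison that crosses the 2 sets of libraries. The count was 1607 with the identities of the library names.

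The group labelled MDA-MB-231 EV, likewise with the other name in the library names, also had higher Ppp1r3g, Pck1 and Tat than PBS. Log2 fold changes were 2.83 for Ppp1r3g (SE 0.58, adjusted p = 0.00264), 1.27 for Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase (SE 0.28, adjusted p = 0.0041), and 1.31 for Tat (SE 0.24, adjusted p = 8.79e-04). Pck1 was at 3970 ± 355 CPM against 1650 ± 749 CPM with PBS (n = 6 each). Of 17 gluconeogenesis genes 5 rose, 6 adjusted over the list alone (camera adjusted p = 0.00939, adjusted p = 0.538 with an estimated correlation). Of 15 glycogen metabolism genes 1 rose and 1 fell, 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.487, adjusted p = 0.862 with an estimated correlation). The heat shock genes Hspa1a, a multi-copy gene (2.36, adjusted p = 0.00222), and Dnajb1 (1.09, adjusted p = 0.00257) were among 4 of 18 that rose, 7 adjusted over the list alone (adjusted p = 0.615 with an estimated correlation). Without PBS replicate 5 Hspa1a had 3.09.

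The surfactant protein gene Sftpa1 (2.09, adjusted p = 6.13e-04), the glycolytic regulator gene Pfkfb3 (1.91, adjusted p = 1.53e-05) and the clock gene Per1 (1.86, adjusted p = 0.00461) rose, and Serpina3a (-5.81, adjusted p = 1.97e-07), Hist1h2ak (-3.37, adjusted p = 1.29e-12), Npas2 (-3.10, adjusted p = 0.0113) and Gadd45a (-1.95, adjusted p = 0.00114) fell. Without PBS replicate 5 Npas2 had -1.48 and did not pass (adjusted p = 0.0858). Of 21 male-biased genes 6 rose, 8 adjusted over the list alone: Cyp7b1 (0.87, adjusted p = 9.62e-04), the complement gene C8a (0.57, adjusted p = 0.00219) and the organic anion transporter gene Slco1a1 (0.44, adjusted p = 0.0101) were among them. Of 20 female-biased genes 3 fell, 10 adjusted over the list alone, such as Cux2 (-1.12, adjusted p = 0.0182) and the steroid hydroxylase gene Cyp17a1 (-0.87, adjusted p = 0.041). With an estimated correlation the adjusted p were 0.549 and 0.538, and with the library names Cyp17a1 had a log2 fold change of 0.36.

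Of 32 acute phase genes 7 rose, 8 adjusted over the list alone, among them Il1r1 (1.11, adjusted p = 1.42e-04), Saa4 (0.58, adjusted p = 1.82e-04) and Hp (0.49, adjusted p = 0.00322) (adjusted p = 0.549 with an estimated correlation). The mesothelial markers Gpm6a (1.78, adjusted p = 0.0212) and Bnc1 (2.26, adjusted p = 0.0328) rose, 2 of 9 on that list with 5 adjusted over the list alone (median 1.78, adjusted p = 0.701 with an estimated correlation). Bnc1 was at 0.571 CPM, and at 0.115 CPM with PBS. In MCF10A EV against PBS the list's median was 1.49, with none of 9 past over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0847, adjusted p = 0.867 with an estimated correlation). The pericentral hepatocyte gene Rgn rose (0.43, adjusted p = 4.67e-04). Of 30 reported miR-122 targets 6 fell and 1 rose, 7 adjusted over the list alone (camera adjusted p = 0.334, fry adjusted p = 0.0875): the glycogen synthase gene Gys1 (-0.65, adjusted p = 0.00113), Hfe2 (-1.01, adjusted p = 0.00172) and Bckdk (-0.51, adjusted p = 0.00239) fell, and P4ha1 rose (1.47, adjusted p = 0.00106). In all, 1607 genes passed, 734 higher and 873 lower, again across the 2 sets. The count was 2463 with the library names and 2879 with limma-voom. Bnc1, Gpm6a and Cyp17a1 also lost their calls without at least 1 library.

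Against MCF10A EV, clock genes set both last groups apart. In the group labelled MCF10A/miR-122 EV, log2 fold changes were 3.07 for Dbp (SE 0.54, adjusted p = 3.58e-04), 3.65 for Usp2 (SE 0.36, adjusted p = 1.73e-07), 2.65 for Wee1 (SE 0.35, adjusted p = 1.27e-05), -2.91 for Arntl (SE 0.40, adjusted p = 1.86e-05) and -4.62 for Npas2 (SE 0.81, adjusted p = 3.76e-04). Of 21 circadian genes 14 were higher and 5 lower, 19 adjusted over the list alone. This list held with an estimated correlation (adjusted p = 0.0238). In the group labelled MDA-MB-231 EV, 14 were higher and 2 lower, 20 adjusted over the list alone, and the list held as well (adjusted p = 0.0151). There, Dbp had 2.87 (adjusted p = 0.00129), Usp2 2.42 (adjusted p = 8.90e-05), Per3 2.30 (adjusted p = 0.00129), Arntl -2.49 (adjusted p = 1.88e-04) and Npas2 was 16-fold lower (adjusted p = 0.00178). Against PBS, Dbp did not pass in the 2 last groups (adjusted p = 0.397 and 0.602). Neither did Per3 (adjusted p = 0.64 and 0.738) or Wee1 (adjusted p = 0.209 and 0.9). Usp2, Arntl and Npas2 passed against PBS in both.

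**Figure D4:**
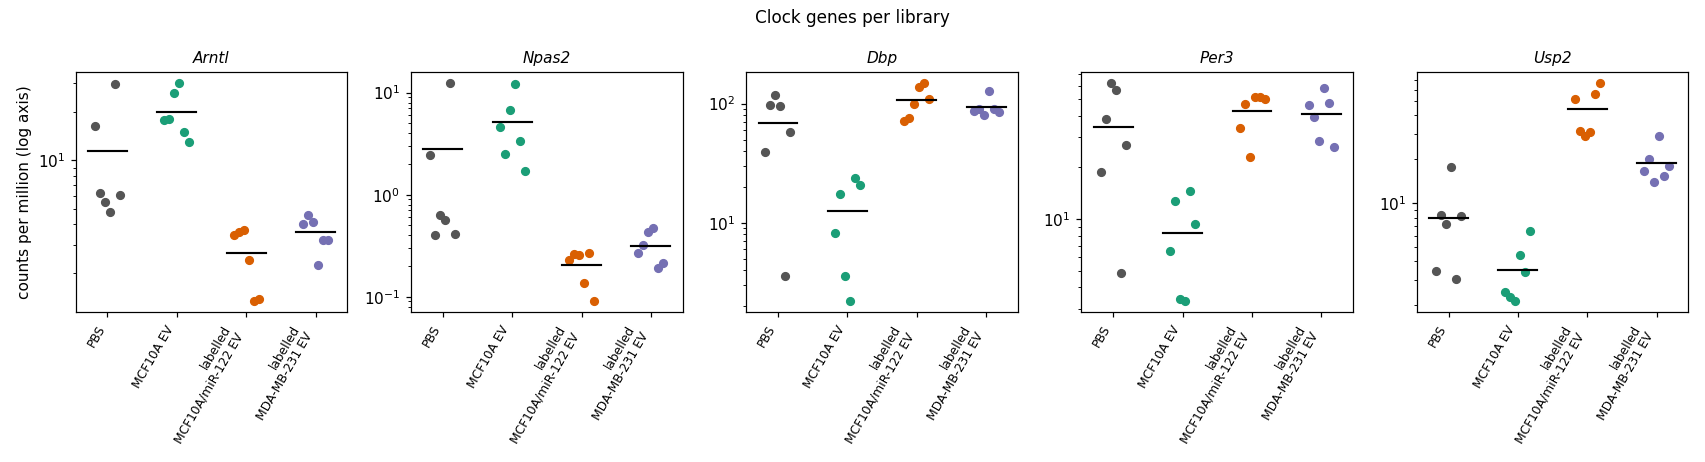
Arntl, Npas2, Dbp, Per3 and Usp2 in CPM (log axes), 1 point per library, with a line at the mean of the 6 libraries of each group as labelled. Dbp averages 68.8 ± 43.2 CPM with PBS and 12.7 ± 9.24 CPM with MCF10A EVs. It averages 107 ± 31.3 CPM in the group labelled MCF10A/miR-122 EV and 93.4 ± 17.1 CPM in that labelled MDA-MB-231 EV.

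Between the groups labelled MCF10A/miR-122 EV and MCF10A EV, Saa3 (4.13, adjusted p = 8.92e-11), the multi-copy gene Cyp2a5 (2.47, adjusted p = 6.84e-07), Tat (1.20, adjusted p = 0.00108) and the cyclin genes Ccnd1 (0.82, adjusted p = 0.00315) and Ccne1 (2.34, adjusted p = 1.61e-04) were higher, and the cyclin-dependent kinase inhibitor gene Cdkn1a (-2.23, adjusted p = 0.0102), the multi-copy urinary protein gene Mup5 (-2.87, adjusted p = 0.0031) and Serpina3a (-7.06, adjusted p = 2.75e-08) lower. Without MCF10A EV replicate 3, at 760 CPM of Mup5, Mup5 had -1.80 (adjusted p = 0.0161), and without MCF10A/miR-122 EV replicate 6 Serpina3a had -8.06. Ccnd1 was at 64.4 ± 17.2 CPM in the first group, 36.6 ± 7.89 CPM with MCF10A EVs and 88.4 ± 12 CPM with PBS. In the same order, Cdkn1a was at 6.39 ± 3.49, 30.1 ± 20.8 and 9.34 ± 12.5 CPM, and Ccne1 at 1.89 ± 0.772, 0.37 ± 0.0801 and 0.84 ± 0.307 CPM. Of 31 cell cycle genes 6 were higher and 2 lower, 16 adjusted over the list alone (adjusted p = 0.679 with an estimated correlation). Of 22 macrophage markers 13 were higher, 17 adjusted over the list alone, such as Vsig4 (0.75, adjusted p = 5.24e-04), Cd5l (0.99, adjusted p = 0.00212; -0.13 with the library names) and Timd4 (0.86, adjusted p = 0.00265) (adjusted p = 0.577 with an estimated correlation). Of 28 genes of the unfolded protein response 14 were lower and 1 higher, 18 adjusted over the list alone (adjusted p = 0.611 with an estimated correlation): the transcription factor gene Atf5 (-0.79, adjusted p = 1.78e-05), the disulfide isomerase gene Pdia4 (-0.54, adjusted p = 4.81e-04) and Calr (-0.47, adjusted p = 5.71e-04) fell and Herpud1, a gene of protein degradation at the endoplasmic reticulum, rose (0.82, adjusted p = 6.12e-04). The multi-copy genes Hsp90aa1 (-0.75, adjusted p = 0.0113) and Rpl34 (-0.57, adjusted p = 4.82e-05) were lower. Of 63 ribosomal protein genes 6 were lower, 6 adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.83 with an estimated correlation), and without multi-copy genes the list turned direction and did not pass (adjusted p = 0.890).

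Among reported miR-122 targets 3 of 30 were lower there, 3 adjusted over the list alone (camera adjusted p = 0.451, fry adjusted p = 0.0652): Smarcd1 (-0.67, adjusted p = 6.93e-04), Bckdk (-0.55, adjusted p = 7.95e-04) and Hfe2 (-0.91, adjusted p = 0.00256). In all, 2237 genes passed, 1037 higher and 1200 lower, and 1058 with the library names. The excess of lower genes turned with RLE size factors (1139 higher and 1108 lower), DESeq2 (1308 and 1235), no filter on low counts (1010 and 983) and only the compared groups (762 and 761).

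Between the groups labelled MDA-MB-231 EV and MCF10A EV, the lipogenic gene Thrsp (1.57, adjusted p = 0.00681), Cyp2a5 (1.53, adjusted p = 5.38e-04), Ccnd1 (0.98, adjusted p = 0.00127), Ccne1 (1.82, adjusted p = 0.00465), Sftpa1 (1.75, adjusted p = 0.00285) and the canalicular export pump gene Abcc2 (0.59, adjusted p = 0.0145) were higher. Cdkn1a (-2.53, adjusted p = 0.00931), Serpina3a (-6.07, adjusted p = 1.04e-07), the ribosomal genes Rpl34 (-0.64, adjusted p = 1.65e-05) and Rps21 (-0.64, adjusted p = 3.73e-04), both multi-copy, Smarcd1 (-0.62, adjusted p = 0.00296) and Gys1 (-0.55, adjusted p = 0.00557) were lower. Ccnd1 was at 72.2 ± 19.7 CPM in the first group, against 88.4 ± 12 CPM with PBS. Cdkn1a was at 5.21 ± 1.73 against 9.34 ± 12.5 CPM, and Ccne1 at 1.32 ± 1.01 against 0.84 ± 0.307 CPM. Of 63 ribosomal protein genes 8 were lower, 11 adjusted over the list alone (adjusted p = 0.761 with an estimated correlation). None of 24 genes of cholesterol synthesis and uptake passed, over all genes or adjusted over the list alone (adjusted p = 0.761 with an estimated correlation). In all, 1058 genes passed, 446 higher and 612 lower, 2237 with the library names and 1643 with limma-voom.

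Over all 18 EV libraries against the 6 PBS libraries, which does not depend on the group names, Lpin1, Pck1 and Tat were higher. Lpin1, a phosphatidate phosphatase gene, rose by a log2 fold change of 1.90 (SE 0.36, adjusted p = 0.00148, 18 of 18 libraries), Pck1 by 1.09 (SE 0.24, adjusted p = 0.00417, 17 of 18) and Tat by 1.08 (SE 0.20, adjusted p = 0.00127, 17 of 18). Of 17 gluconeogenesis genes 7 rose, 8 adjusted over the list alone, with Ppargc1a at 1.01 (adjusted p = 0.0101, 17 of 18) and Slc37a4 at 0.49 (adjusted p = 0.00194) (list adjusted p = 0.355 with an estimated correlation). In MCF10A EV against PBS, within the first set, none of the 17 passed, over all genes or adjusted over the list alone (median 0.17, camera adjusted p = 0.0891, adjusted p = 0.576 with an estimated correlation). Of 32 acute phase genes 14 rose, 16 adjusted over the list alone: Il1r1 (1.14, adjusted p = 1.71e-05), Hp (0.66, adjusted p = 2.52e-05) and Saa4 (0.49, adjusted p = 1.77e-04) in 18 of 18 libraries (list adjusted p = 0.324 with an estimated correlation). Of 18 heat shock genes 5 rose, 9 adjusted over the list alone (adjusted p = 0.552 with an estimated correlation), with Dnajb1 at 0.89 (adjusted p = 0.00386). Ppp1r3g (2.46, adjusted p = 0.00367, 16 of 18), Igfbp1 (1.75, adjusted p = 0.0422, 16 of 18) and the transcription factor gene Zbtb16 (1.74, adjusted p = 0.0286) rose. Lpin1 had 2.50 without PBS replicate 6, and Zbtb16 3.01 without PBS replicate 5.

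Falls were Gadd45a (-1.62, adjusted p = 3.57e-04), the Wnt receptor gene Fzd6 (-1.32, adjusted p = 4.92e-06), Cd274, which encodes PD-L1 (-1.08, adjusted p = 3.03e-05), and the thyroid hormone deiodinase gene Dio1 (-1.16, adjusted p = 0.0326, 17 of 18). Of 31 cell cycle genes 12 fell, 16 adjusted over the list alone (adjusted p = 0.612 with an estimated correlation), with Cdc20 at -1.74 (adjusted p = 0.00284). Of 39 interferon-stimulated genes 8 fell, 10 adjusted over the list alone (adjusted p = 0.72 with an estimated correlation), with Cxcl10 at -0.96 (adjusted p = 0.00523) and Tap1 at -0.55 (adjusted p = 0.00281), each in 17 of 18 libraries. Cux2 was 2.01-fold lower (adjusted p = 0.00686, 15 of 18). Of 30 reported miR-122 targets 6 fell and 1 rose, 7 adjusted over the list alone (camera adjusted p = 0.282, fry adjusted p = 0.0666): the AMP kinase subunit gene Prkab1 (-0.42, adjusted p = 0.0019), Bckdk (-0.39, adjusted p = 0.00347, 14 of 18) and Hfe2 (-0.74, adjusted p = 0.00284, 16 of 18) fell and P4ha1 rose (1.15, adjusted p = 0.00226). In all, 1734 genes passed, 747 higher and 987 lower, 1058 without PBS replicate 1 and 2745 with limma-voom. Igfbp1, Zbtb16 and Dio1 lost their calls without at least 1 library. Over the 4 groups, 2945 genes differed between any of them.

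With the preset correlation, 10, 9, 14, 14, 11, 7 and 14 of 35 lists passed for all EVs, MCF10A EV, MCF10A/miR-122 EV and MDA-MB-231 EV against PBS, for the last 2 groups against MCF10A EV, and for the last 2 against each other, all as labelled. Random regroupings of the same libraries gave as many in 61, 76, 23, 36, 50, 88 and 17 of 100 splits. With an estimated correlation 0, 0, 0, 0, 1, 1 and 0 passed.

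The groups labelled MCF10A/miR-122 EV and MDA-MB-231 EV shared 530 genes higher and 664 lower against PBS, where independent lists would share 61.3 and 83.2. With separate PBS libraries for each, 3 and 3, the medians were 142 and 242. MCF10A EV shared 33 higher and 39 lower with the first of them and 31 and 43 with the second (4.26 and 9.15, and 2.72 and 6.08, for independent lists), and 3 and 2.5 with separate PBS libraries. Against MCF10A EV the 2 last groups shared 345 higher and 508 lower (33.6 and 53.3 for independent lists, 85.5 and 196 with separate controls). Tests with 3 control libraries have less power than those with 6, on which the numbers for independent lists rest. These 2 kinds of count therefore cannot be set against each other. With separate controls the median correlation of log2 fold changes across genes was 0.652 for the 2 last groups against PBS and 0.642 against MCF10A EV. For MCF10A EV against PBS it was 0.169 with the first of them and 0.248 with the second. Simulated groups without effect shared 0, which says little, since such groups have few calls to share. The overlaps of the 2 last groups come from comparisons that cross the 2 sets of libraries. A difference between the sets could therefore give them.

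Genes with a match to the miR-122 seed in their annotated 3' UTR (1206, against 11682 without) showed no shift past the threshold against the others in the 7 comparisons (camera p 0.136 to 0.709, adjusted p 0.438 to 0.853). Among the 4 other seeds tested, genes with a miR-21 match (989) were higher in the group labelled MDA-MB-231 EV than in MCF10A EV, with medians of 0.07 and -0.00 (camera adjusted p = 0.0227, p = 0.0898 with an estimated correlation). With 8mer matches alone (289 genes) they did not pass (camera adjusted p = 0.0804, p = 0.112 with an estimated correlation), and with 7mer-m8 or 7mer-A1 matches (1577 genes) they did (camera adjusted p = 0.0344, p = 0.0847 with an estimated correlation). This comparison crosses the 2 sets, and the miR-9 and miR-124 seeds moved the same way (differences of medians 0.039 and 0.037, camera adjusted p = 0.283 each). The miR-21 difference was 0.067 for MCF10A/miR-122 EV against MCF10A EV and -0.056 for MCF10A EV against PBS (camera adjusted p = 0.122 and 0.17). Between the 2 last groups it was 0.001 (camera adjusted p = 0.853).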

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

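The tests of the 3 patterns weighed here (genes that differ between the 2 sets of 12 libraries, clock genes and serum amyloid A genes) were chosen only after the results were seen, and the test of the time of day, first made against MCF10A EV alone (12 of 12 clock genes with the sign of a shift), was then changed to need PBS as well. A test of it as the whole cause, on the circadian list between MCF10A EV and PBS, was tried with the count of clock genes past the threshold (3), with camera (adjusted p = 0.455 with an estimated correlation) and then with fry (mixed directions, adjusted p = 0.00434), and nothing is drawn from it, since it does not test the genes that differ between the sets. The alternative without PBS replicate 5 and MCF10A EV replicate 4 was also chosen then.

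A library was singled out where its gap to the nearest of the other 5 in its group was, as a share of the group's range, over Dixon's 95% critical value for 6 values. This held for 31 of 412 groups of values (7.52%), where chance gives about 1 in 20, or 20.6. PBS replicate 5 accounts for 8 of them. Its ratios were 0.682 for Dbp (log2 CPM 1.86, others 5.29 to 6.89), 0.680 for Hspa8 (high), 0.707 for Ppargc1a (high), 0.634 for P4ha1 (high), 0.769 for Zbtb16 (high) and 0.699 for Fzd6 (low). For the nuclear RNA Malat1 it was 0.776 (922 CPM, others 249 to 399) and for the ribosomal RNA precursor Rn45s 0.810 (1239 CPM, others 185 to 385). MCF10A EV replicate 4 stood out for the same RNAs, Malat1 with 0.697 (1030 CPM, others 228 to 471) and Rn45s with 0.870 (1597 CPM, others 236 to 413). MCF10A EV replicate 5 had 0.641 for Pck1 (low), 0.641 for Hsp90aa1 (high) and 0.691 for Lpin1 (low).

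PBS replicate 3 had 0.705 for Saa3 (high) and 0.891 for Dio1 (low), and PBS replicate 6 had 0.692 for Serpina3a and 0.726 for Pfkfb3 (both high). In the group labelled MCF10A/miR-122 EV, replicate 3 had 0.695 for Itih3, 0.764 for Ppp1r3g, 0.663 for Pck1 and 0.860 for Rps21 (all high), and replicate 4 had 0.799 for Abcc2 (low). In the group labelled MDA-MB-231 EV, replicate 1 had 0.703 for Hist1h2ak (low). Replicate 2 had 0.676 for Cux2 and 0.721 for the TMM factor (both low), replicate 3 had 0.675 for Saa2 and 0.664 for Saa1 (both high), and replicate 4 had 0.729 for Dbp (high). Replicate 6 had 0.693 for Il1r1 and 0.688 for Ccne1 (both high) and 0.681 for Prkab1 (low).

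By direct tests between EV groups, in which PBS cancels, 2237 genes differed between the groups labelled MCF10A/miR-122 EV and MCF10A EV. The tests gave 1058 genes for MDA-MB-231 EV and MCF10A EV, and 35 for MDA-MB-231 EV and MCF10A/miR-122 EV. Only the last of these lies within a set of libraries. In the other comparisons the set and the EVs given cannot be told apart.

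In both groups of the last 12 libraries, 294 genes were lower than in both groups of the first 12, and 139 were higher. Lower depth is argued against, since the last 12 libraries held 1.19 times the counts of the first 12. Reads shared between near-identical genes are a candidate explanation for part of the falls: 35.5% of the falls with a reference sequence were multi-copy genes, against 14.5% of other tested genes (Fisher's exact p = 2.8e-18). Another 34.5% of these falls share no exact 32-mer with another gene. For those, shared reads are argued against but not excluded, since only the longest transcript per gene in an annotation of another build was searched. A difference in how reads were counted in the 2 sets stays open, as 1 gene (Gm20594) was at 0 in all 12 libraries of one set and at 20 counts or more in all 12 of the other, too few to decide. The treatment itself stays open too, and cannot be told apart from the sets, since 0 groups had libraries in both.

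Clock genes differed in part between the sets and in part within the first. Of 16 clock genes with a known phase, 12 passed in both last groups against MCF10A EV and 6 against PBS, while 3 others (Dbp, Per3 and Wee1) and 0 of the 6 passed between MCF10A EV and PBS. Reads shared between genes are argued against, since 16.7% of the 6 were multi-copy. Another time of day for the last 12 libraries stays open: 100% of the 6 had the sign of such a shift, too few to decide. Whether the time of day also differed between MCF10A EV and PBS stays open too. An effect of the EVs given to the last groups cannot be told apart from the sets, with 0 groups in both.

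For the serum amyloid A genes, a rise carried by 1 or 2 libraries is argued against, since 6 of 6 libraries of the group labelled MCF10A/miR-122 EV lay above the other 18. The difference between the sets is argued against by the contrast within the last 12 libraries (Saa3 log2 fold change -4.04). More macrophages, as the source of this RNA, would need their markers to move about as far, and their median moved by -0.38 in the same contrast. An effect of macrophages on the serum amyloid A RNA of other cells was not tested and stays open. Which EVs these mice received stays open, as 0 of the 6 library names match the title.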

How the results depend on the processing

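The settings without multi-copy genes and without PBS replicate 5 and MCF10A EV replicate 4 were chosen only after the results were seen. Where a count moved, the cause was not tested, except that the library names exchange 2 groups by construction and the 2-fold limit removes smaller changes by construction.

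With limma-voom and quality weights the genes past the threshold were 2745 for all EVs against PBS, 837 for MCF10A EV, 2879 for MDA-MB-231 EV, 1643 for MDA-MB-231 EV against MCF10A EV, 221 for MDA-MB-231 EV against MCF10A/miR-122 EV and 4988 for any group. DESeq2 gave 414 for MCF10A EV against PBS, with 146 of the 147, and 98 for the last pair, with 35 of the 35. Only the compared groups gave 27, with 23 of the 147, and 23, with 15 of the 35. The strict filter gave 15 for the last pair. Without PBS replicate 5 and MCF10A EV replicate 4, 412 passed for MCF10A EV against PBS, with 140 of the 147. With a limit of 2-fold, 169, 38, 342, 256, 307, 163 and 20 passed, in the order all EVs, MCF10A EV, MCF10A/miR-122 EV and MDA-MB-231 EV against PBS, the last 2 against MCF10A EV, and these 2 against each other. With the library names, MCF10A/miR-122 EV had 1607 against PBS and 1058 against MCF10A EV, and MDA-MB-231 EV 2463 and 2237.

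Lists past camera numbered 0, 0, 0, 0, 1, 1 and 0 with an estimated correlation, in the same order. Fry gave 3 and 3 for the last 2 comparisons. Without multi-copy genes 9 passed for MCF10A/miR-122 EV against PBS and 6 against MCF10A EV, where the ribosomal list turned direction (adjusted p = 0.890).

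With the library names the 22 named genes of the last comparison turned by construction: Saa3 4.04, Saa2 3.92, Saa1 3.88, Amica1 2.69, BC018473 2.01, Lcn2 1.49, Cyp17a1 1.24, Kcna2 1.19, Emr1 1.13, Cd5l 1.12, Marco 1.04, Cyp2a5 0.94, Vcam1 0.92, Vsig4 0.65, Sds 0.55, Fermt2 -0.33, Hspa1a -0.80, Cyp7b1 -0.82, Gp49a -0.83, Fam198a -1.18, Hsd3b5 -1.24 and Cyp8b1 -1.31. So did Saa3 (-0.0014), Vsig4 (-0.035) and Marco (-0.070) in MCF10A/miR-122 EV against PBS, Cyp17a1 (0.36) in MDA-MB-231 EV against PBS and Cd5l (-0.13) in MCF10A/miR-122 EV against MCF10A EV.

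Leaving out 1 library at a time gave 1058 to 1977 genes for all EVs (1058 without PBS 1), 26 to 741 for MCF10A EV, 1821 to 2613 for MCF10A/miR-122 EV and 1132 to 1693 for MDA-MB-231 EV against PBS, 1653 to 2575 and 711 to 1125 against MCF10A EV, 13 to 82 for the last pair and 2453 to 3286 for any group. For MCF10A EV against PBS the count was 71, 75, 26, 61 and 741 without PBS 1 to 5, and 88, 97, 64 and 57 without MCF10A EV 1, 2, 4 and 6. For the last pair it was 13, 82, 54 and 21 without MCF10A/miR-122 EV 3, 4, 5 and 6, and 17, 18 and 19 without MDA-MB-231 EV 2, 3 and 5. Lists numbered 10 to 16 (16 without PBS 4), 9 to 12, 10 to 16, 11 to 17, 8 to 15, 5 to 10 and 13 to 17. Of 163 named calls, 133 held without any 1 library, 30 were lost without at least 1 and 0 reversed. In the fit of only the compared groups 23 named calls were lost, with the replicate block 7 and with limma-voom 4. With the library names 22 were lost without a turn of direction.

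Replicate numbers did not pair the samples: the 36 pairs of libraries with the same number had a mean r of 0.0376 (-0.43 to 0.374), and 4 of 24 libraries were nearest to one of their own number. With the number as a block, 1771, 165, 2500, 1714, 2356, 1155 and 35 genes passed.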

Other observations

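The regroupings of libraries and the list of 11 glucocorticoid-responsive genes had their predictions written before their results were seen, and the regroupings for lists were added once those for genes were known.

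A hypothesis was that livers of EV-treated mice may show stronger glucocorticoid signaling, since Tsc22d3, Zbtb16 and Lpin1 were higher. The median log2 fold change of the 11 genes was 0.20 for MCF10A EV against PBS, with 0 past the threshold (adjusted p = 0.563 with an estimated correlation), which leaves the hypothesis undecided within the first set. For the group labelled MCF10A/miR-122 EV against PBS it was 0.65, with 6 genes higher (adjusted p = 0.0825 with an estimated correlation), and for MDA-MB-231 EV 0.49 (adjusted p = 0.378), both across the sets. For all EVs against PBS, in part across them, it was 0.40, with 4 genes higher (adjusted p = 0.179 with an estimated correlation), and for MDA-MB-231 EV against MCF10A/miR-122 EV, within the last set, -0.49, with 0 past the threshold (adjusted p = 0.0825 with an estimated correlation).

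Random regroupings of the same libraries, 100 for each comparison with the real one included, seldom gave as many genes as the real groups. For all EVs against PBS, for any group and for the comparisons that cross the 2 sets of libraries, the regroupings mixed the sets. A difference between the sets alone could give such a result there, so nothing is drawn from it about the treatment. All EVs against PBS had 1734 genes, reached by 1 split (highest other 2), MCF10A/miR-122 EV 2463 (1 split, highest other 1552), MDA-MB-231 EV 1607 (1 split, highest other 403), MCF10A/miR-122 EV against MCF10A EV 2237 (1 split, highest other 1330), MDA-MB-231 EV against MCF10A EV 1058 (1 split, highest other 46), MDA-MB-231 EV against MCF10A/miR-122 EV 35 (1 split, highest other 3) and any group 2945 (1 split, highest other 21). For MCF10A EV against PBS 147 genes were reached by 3 splits, the real one included, and the highest of these gave 634, several times the real count. That split kept 10 of 12 labels, exchanging PBS replicate 5 and MCF10A EV replicate 2, and points to a structure of the samples. PBS replicate 5 also stood out from its group for Dbp, Malat1 and Rn45s, and 741 genes passed without it. The cause was not tested.

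For the lists past camera with the preset correlation chance was not excluded. All EVs against PBS had 10 lists, reached by 61 splits (highest other 17), MCF10A EV 9 (76 splits, highest other 19), MCF10A/miR-122 EV 14 (23 splits, highest other 18), MDA-MB-231 EV 14 (36 splits, highest other 18), MCF10A/miR-122 EV against MCF10A EV 11 (50 splits, highest other 19), MDA-MB-231 EV against MCF10A EV 7 (88 splits, highest other 18) and MDA-MB-231 EV against MCF10A/miR-122 EV 14 (17 splits, highest other 18).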
